A study of Mus musculus with 4 samples.

How the data were processed

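RNA was measured in RAW264.7 cells, a mouse macrophage-like line, after transfection with a non-targeting control siRNA or a pool of siRNAs against Ruvbl2 and treatment with LPS (lipopolysaccharide, a bacterial cell wall component sensed by Toll-like receptor 4) or DMSO. There were 4 groups with 1 array each, hybridized in 1 colour to a whole-genome Agilent mouse array. Both Ruvbl2 sample titles spell the target with a letter missing, and it was taken as Ruvbl2 because the series description names RUVBL2. The labels' protocols name electroporation or a lipid reagent for transfection without saying which was used for these samples. The dose and duration of LPS are not given in the sources used here.

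Per the file headers, the 4 arrays lay on 1 slide, were scanned on 1 day and were read with Agilent Feature Extraction 11.5.1.1, while the submitters' processing notes name version 11.0. The deposited values are intensity values per the file headers: the processed signal is the spot's brightness after background subtraction and detrending within the array, not on a log scale and not normalized between arrays. The deposited value table of the series, also intensity, was checked against the scanner output and equalled the processed signal at all 62976 spots of each array. The array carried 3671 control spots and 56605 distinct probes for RNA, of which 300 were printed 10 times. Probes were given gene symbols through the RefSeq transcript accession in the array annotation and a mouse gene table. This named 32994 probes and 22911 genes, of which 15012 had 1 probe and 7899 had several. The remaining 23611 probes had no symbol and were counted apart. The array annotation and the gene table rest on different genome builds, so no positions are given.

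Replicate spots of a probe were averaged after leaving out spots that the scanner software marked as population outliers. The log2 processed signal minus the array's 75th percentile over all probes is called the level, so that 0 is the 75th percentile. Each gene was represented by its probe with the highest mean level over the 4 arrays. A probe was called well above background where the scanner software did so for its spot, or for at least as many of its spots as not, and 12471 genes were well above background on all 4 arrays and 13957 on at least 1. A difference was called when it reached 1 on the log2 scale (2-fold) between arrays on which the gene was well above background. Where a gene was well above background on the brighter array alone, the dim array was set to the higher of its own value and its floor. The difference is then called a bound and given as "at least N-fold". Where the dim value itself lay above the floor, it is a plain difference against an undetected value and not a lower limit. Genes dim on both arrays were not compared. The floor was the lowest level of any probe well above background on that array. With 1 array per group there is no replicate error, no residual degree of freedom and no p-value, and the number of arrays limits the precision of every value. Technical error within an array was taken from the probes printed 10 times: the SD of a log2 difference was 0.49 for levels from -6 to -4, 0.27 from -4 to -2 and 0.06 above 3.

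The comparisons were LPS against DMSO with each siRNA, Ruvbl2 siRNA against control siRNA in each treatment, the difference between the LPS effects with each siRNA, and the agreement of effects from separate pairs of arrays. The difference of LPS effects was computed for genes well above background on all 4 arrays. There were 24 gene lists, covering inflammatory, interferon, stress, metabolic, cell cycle, RUVBL complex and cell type genes. A list's median log2 difference was set against 10000 random lists of the same size matched on mean level in 20 bins, and a list was called apart when 2.5% or fewer of the random lists lay beyond it on its side. Lists with fewer than 5 compared members were given no median. List members are not independent replicates, so these percentiles describe the list on these arrays and not the variation between cultures.

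The comparisons, size rule, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. The named genes of each comparison were Ruvbl2 and Ruvbl1; a panel of Tnf, Il6, Il1b, Il12b, Nos2, Ptgs2, Cxcl2, Ccl2, Cxcl10 and Ifnb1; the 10 largest measured differences per direction among called genes that kept their direction after normexp correction and quantile normalization, leaving out clone, Gm and LOC symbols; up to 3 genes per direction with the largest bound; and up to 2 members per direction of each list. The text names genes from the top of these rankings.

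Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, centring on the median of probes well above background on all arrays, cyclic loess, the deposited value table, the mean of a gene's probes, leaving out spots marked non-uniform or saturated, other filters on dim genes, size thresholds of 0.58 and 2, and random lists matched on the control LPS array. The scanner output held no mean spot signal, so normexp used the median spot and local background signals. Scaling on Agilent's E1A spike-in probes, a filter on the brighter array and a version with dim values set to the floor were added after seeing the data. The procedure was tested on simulated data built from these arrays for the Ruvbl2 siRNA difference in LPS: 99 of 100 genes set 1.5 apart on the log2 scale and 100 of 100 genes set 3 apart were recovered in the right direction. Of 13227 genes left unchanged there, 93 were called, all of them below a level of -2, and 12 of 200 unchanged lists fell outside the central range. The simulated noise was the spread of replicate spots within an array, independent between genes, with no variation between arrays or cultures. These figures therefore check the procedure and do not give the rate of false calls between single cultures. Computation used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, R 4.3.3 with limma 3.58.1 for normexp, quantile and loess normalization, and matplotlib 3.10.9.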

Results

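Messenger RNA was profiled in RAW264.7 mouse macrophage-like cells that carried a control siRNA or an siRNA pool against Ruvbl2 and had been given DMSO or LPS. RUVBL2 is an AAA+ ATPase that works with RUVBL1 in chromatin remodelling complexes and in a chaperone complex, and the series asks about its role in the expression of proinflammatory genes after LPS. Each of the 4 groups was 1 array, so no value could be checked against a replicate. The share of RNA spots well above background was alike: 55.0% on the control siRNA DMSO array, 54.1% on the control siRNA LPS array, 54.3% on the Ruvbl2 siRNA DMSO array and 54.2% on the Ruvbl2 siRNA LPS array. The 75th percentile of the processed signal was 456, 395, 331 and 407 in the same order, and no spot was saturated. Both control siRNA arrays lay in row 1 of the slide and both Ruvbl2 siRNA arrays in row 2, so slide row and siRNA cannot be told apart. Relative to each array's 75th percentile, the E1A spike-ins, RNA of known amount added before labelling, were higher on the Ruvbl2 siRNA DMSO array than on the control siRNA DMSO array. The median difference was 0.27 on the log2 scale (7 probes, 0.20 to 0.32). The median spike-in levels used for scaling were 3.95 and 3.64 on these arrays. Scaling on them in place of the 75th percentile moved the median of all genes to -0.27 for the siRNA difference in DMSO, to 0.34 for LPS with Ruvbl2 siRNA and to 0.28 for the difference in LPS response, and gene and list directions that turn with it are named where they occur.

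Ruvbl2 mRNA read lower with its siRNA in both treatments, by a small amount that only the brighter probe in LPS set apart. The brighter of its 2 probes, A_55_P2025974, stood at 79.2% of control in DMSO (log2 difference -0.34, or -0.65 with spike-in scaling) and at 75.7% in LPS (-0.40), against a technical SD of 0.06. Of 500 probes of similar brightness, 24 were as low or lower in DMSO and 9 in LPS. The dimmer probe, A_55_P2928822, differed by -0.55 in DMSO and by -0.12 in LPS, with technical SDs of 0.22 and 0.27. Of 500 probes of its brightness, 23 were as low or lower in DMSO and 178 in LPS, so its LPS value does not show a fall. Ruvbl1, the partner ATPase, differed by 0.00 in DMSO (-0.31 with spike-in scaling) and by 0.14 in LPS. Neither Ruvbl2 difference reached the 2-fold size rule. With control siRNA, LPS against DMSO gave -0.09 for the brighter Ruvbl2 probe and -0.64 for the dimmer, with technical SDs of 0.06 and 0.22.

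What LPS did in cells with control siRNA was read from the LPS and DMSO arrays of that siRNA, and the inflammatory programme of the macrophage was much higher with LPS. Ccl2, a chemokine for monocytes, was 135-fold higher, and Nos2, the inducible nitric oxide synthase, was 48.8-fold higher. Cxcl2, a chemokine for neutrophils, was 30.0-fold higher, Ptgs2, the inducible cyclooxygenase, 14.5-fold, and the cytokine Tnf 3.92-fold. Il1b and Il6, cytokines of fever and the acute phase, were not well above background in DMSO. Il6 was at least 13.4-fold higher with LPS. Il1b was 233-fold higher, a plain difference and not a lower limit, since its undetected DMSO value lay just above the floor (-5.12 against -5.15). Cxcl10, an interferon-inducible chemokine, was 1.43-fold higher and Ifnb1 at least 1.86-fold, and neither passed the size rule. Il12b was well above background on the control siRNA DMSO array alone, just over the floor.

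Of the genes compared with control siRNA, 776 were higher and 298 lower with LPS. Large measured differences included Upp1, a uridine phosphorylase (142-fold), Siglec1, a sialic acid receptor of macrophages (138-fold, or a log2 difference of 7.11, against 5.16 by its other measured probe), the iron-scavenging protein gene Lcn2 (108-fold), the formyl peptide receptor Fpr2 (104-fold) and Acod1, which makes itaconate (36.1-fold). Pdpn, a mucin-type membrane protein, was at least 599-fold higher. On the lower side stood Dgkg, a diacylglycerol kinase (16.5-fold lower), Hpgd, which breaks down prostaglandins (11.7-fold lower), and Il4i1, an amino acid oxidase (9.10-fold lower). Of 24 later proinflammatory genes compared, 16 were higher and 0 lower, with a median of 1.91, and of 15 chemokine genes 11 were higher, with a median of 2.97. Among 47 interferon-stimulated genes, 29 were higher, led by the nucleic acid sensor Zbp1 (32.9-fold) and the ubiquitin-like modifier Isg15 (8.80-fold). The primary response list had a median of 0.81, with 12 of 29 members higher, and the anti-inflammatory list one of 0.68, with Socs3, an inhibitor of cytokine signalling, 23.3-fold higher and Il1rn, the interleukin-1 receptor antagonist, 20.4-fold. Genes of the NF-kB family and its feedback had a median of 0.29, with the nuclear IkB protein gene Nfkbiz 6.22-fold higher, and Toll-like receptor 4 signalling genes one of 0.06, inside the range of random lists. The counts were 451 higher and 150 lower with normexp correction and quantile normalization. Of 295 other measured probes of called genes, 257 had the same direction and 145 passed the size rule in it.

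In cells with Ruvbl2 siRNA, many of the same genes stood higher with LPS. Ccl2 was 82.8-fold higher, Nos2 24.8-fold, Cxcl2 11.3-fold and Ptgs2 5.07-fold, while Tnf was higher by 2.00 on the log2 scale. Il1b was at least 73.3-fold higher and Il6 at least 2.44-fold, the latter under 2-fold with normexp correction and with the mean of its probes. These bounds rest on a higher floor (-4.83, against -5.15 on the control siRNA DMSO array), so their sizes cannot be set against those with control siRNA. Cxcl10 was 2.34-fold higher, past the size rule here, and Ifnb1 at least 1.48-fold, not past it. Siglec1 was 52.6-fold higher, Lcn2 48.2-fold, the matrix metalloproteinase gene Mmp9 39.3-fold and the T cell chemokine gene Ccl5 31.1-fold. Dgkg was 12.6-fold lower and Hpgd 7.49-fold lower.

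With Ruvbl2 siRNA, 559 genes were higher and 280 lower with LPS. Of all genes compared, 544 passed the size rule in the same direction with both siRNAs, 410 higher and 134 lower. If every gene were equally likely to pass it, 27.5 and 5.39 would be shared by chance. Only 2 genes passed it in opposite directions. Across 12471 genes, which are not independent replicates, the LPS differences with each siRNA had a Pearson r of 0.82 and a Spearman rho of 0.69. The least-squares slope of the Ruvbl2 siRNA values on the control values was 0.71. Noise in the control values lowers such a slope by itself, so it does not measure a weaker response. The list medians were 1.5 for later proinflammatory genes, 2.56 for chemokines, 0.57 for primary response genes, 0.56 for anti-inflammatory genes and 0.20 for NF-kB genes, each above its random range. Interferon-stimulated genes had a median of 1.45, with 38 of 48 members higher. The share of called genes that were higher was 66.6%, and 90.3% with spike-in scaling, which gave 1104 higher and 119 lower. With normexp correction and quantile normalization the counts were 298 and 117.

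Without LPS, the clearest difference between the siRNAs lay in interferon-stimulated genes, which were lower with Ruvbl2 siRNA. Of 46 members compared, 43 lay below 0 and 8 passed the size rule as lower and 0 as higher, with a median of -0.63 against a random range of -0.03 to 0.11. Oasl2, a member of the antiviral oligoadenylate synthetase family, was 2.44-fold lower, Isg20, an antiviral exonuclease, 2.43-fold and Cxcl10 2.13-fold, and outside the list Ifi44l, an interferon-induced gene, was 3.68-fold lower. Glycolysis and hypoxia genes were also lower, with a median of -0.24 and 30 of 34 members below 0, among them Adm, the gene of the vessel-dilating peptide adrenomedullin (2.39-fold lower). Higher with Ruvbl2 siRNA were Acp5 and Ctsk, an acid phosphatase and a protease of osteoclasts (2.86-fold and 2.26-fold), Phlda3, a p53 target that restrains Akt (2.65-fold), and Cd207, the Langerhans cell lectin langerin (5.79-fold). Cxcl10 apart, the proinflammatory panel was close between siRNAs in DMSO where it could be compared: Tnf differed by -0.01, Nos2 by -0.06, Ptgs2 by 0.19 and Ccl2 by 0.29, the last pair below 0 with spike-in scaling (-0.12 and -0.03), and Cxcl2 by -0.38.

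In DMSO 136 genes were higher and 72 lower with Ruvbl2 siRNA, the smallest set of the 4 pairwise comparisons. Of these, 54 higher and 56 lower were measured on both arrays, while 82 higher and 16 lower were bounds. The excess of higher calls thus lay in the bounds. The floor was -5.15 on the control siRNA DMSO array and -4.83 on the Ruvbl2 siRNA DMSO array, so higher bounds had more room than lower ones. Large measured differences included Slc35b4, a nucleotide sugar transporter (5.96-fold higher), Syt10, a synaptotagmin (8.61-fold lower), and Aldh3a1, an aldehyde dehydrogenase (5.68-fold lower). The Ruvbl2 siRNA DMSO array stood apart from the other 3 for these: Syt10 had a level of 0.30 there and of 2.98 to 3.41 elsewhere. Cma1, a mast cell protease gene, was at least 15.6-fold higher and was well above background on that array alone. Primary response genes (0.10), later proinflammatory genes (-0.05), chemokines (-0.06), NF-kB genes (0.03), anti-inflammatory genes (0.00) and Toll-like receptor 4 signalling genes (0.02) had medians inside their random ranges, those above 0 turning negative with spike-in scaling, although Atf3, a stress-induced transcription factor gene, was 2.27-fold lower and Saa3, an acute phase protein gene, 2.26-fold higher. The lists of p53 targets (0.17), NRF2 and oxidative stress genes (0.17), macrophage identity genes (0.22) and osteoclast genes (0.22) were above their random ranges, and with spike-in scaling their medians were negative (-0.14, -0.14, -0.093 and -0.09), as was that of all genes. The osteoclast list came within its range with normexp correction and quantile normalization and with the mean of probes. Hmox1, heme oxygenase 1, was 2.19-fold lower within the oxidative stress list. Most of these calls were near the floor: 26 higher and 34 lower were left when the brighter array had to reach a level of -2, and 14 and 24 with normexp correction and quantile normalization, under which Oasl2, Ctsk, Saa3 and Cd207 were under 2-fold, as Ctsk and Saa3 were with spike-in scaling. The share of calls that were higher was 65.4%, against 36.8% with normexp correction and quantile normalization and 23.5% with spike-in scaling. Few called genes had another measured probe: of 12 such probes, 9 had the same direction and 6 passed the size rule in it.

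The comparison closest to the question of the series is that of the siRNAs under LPS, where many induced inflammatory genes were lower with Ruvbl2 siRNA and Tnf was not. Il6 was 4.39-fold lower, Cxcl2 3.48-fold, Il1b 2.61-fold, Ptgs2 2.51-fold and Nos2 2.05-fold, the last under 2-fold with normexp correction and quantile normalization. Tnf differed by 0.02 and Ifnb1 by -0.01, the latter near the floor, while Ccl2 was 1.34-fold and Cxcl10 1.30-fold lower, neither past the size rule, and Il12b was not well above background on either LPS array. Later proinflammatory genes had a median of -0.52 against a random range of -0.20 to 0.17: of 23 compared, 21 lay below 0, 8 were called lower and 1 higher. Cfb, complement factor B, was 4.83-fold lower and Csf3, a growth factor for granulocytes, 4.26-fold lower, while Mmp9 was 2.10-fold higher.

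The other inflammatory lists lay below their random ranges as well. Primary response genes had a median of -0.23, with 6 of 29 called lower and 0 higher, among them Atf3 (3.64-fold lower). Chemokines had a median of -0.42, with 4 of 15 lower, including Ccrl2, an atypical chemokine receptor (2.80-fold lower). Interferon-stimulated genes had a median of -0.36, with 34 of 48 below 0, and Isg20 was 3.55-fold and Ifit3, an antiviral RNA-binding protein gene, 2.29-fold lower. In the same list Ifi205 was at least 2.07-fold higher, though under 2-fold with normexp correction and quantile normalization. NF-kB genes had a median of -0.18, with Nfkbiz 2.42-fold lower. The anti-inflammatory and negative feedback list was lower too, with 18 of 26 members below 0, and its Il10, an anti-inflammatory cytokine, was 4.64-fold lower and Maf, a transcription factor that drives Il10, 3.92-fold lower. Toll-like receptor 4 signalling genes had a median of 0.02, with 0 of 43 members past the size rule.

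Some of the stress and metabolic lists differed under LPS as well. The ATF4 and unfolded protein response list had a median of -0.22, with 5 of 42 members called lower and 0 higher, including Trib3, a pseudokinase gene (2.96-fold lower), and Pck2, the mitochondrial phosphoenolpyruvate carboxykinase (2.75-fold lower). Glycolysis and hypoxia genes had a median of -0.37, with 31 of 33 below 0, including the enolase gene Eno2 (3.41-fold lower) and the hypoxia-inducible gene Ndrg1 (2.91-fold lower). Higher with Ruvbl2 siRNA were Hspa1b, an inducible heat shock protein 70 (5.01-fold), the receptor tyrosine kinase gene Epha2 (4.83-fold), Phlda3 (4.14-fold) and Ctsk (3.27-fold). Not all p53 targets were higher: Plk2 was 2.46-fold lower and Gdf15 at least 2.24-fold lower, both under 2-fold with normexp correction and quantile normalization. The p53 target list (0.21), the osteoclast list (0.22), the RUVBL1/RUVBL2 chromatin complexes (0.12), the R2TP chaperone, TTT complex and PIKK client list (0.13) and the cell cycle list (0.13) were above their random ranges by small amounts, and macrophage identity genes were below theirs (-0.12). NRF2 and oxidative stress genes (0.08) were within it. The RUVBL complex list had 26 of 34 members above 0, none past the size rule, and came within the range with quantile normalization.

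Under LPS 143 genes were higher and 197 lower with Ruvbl2 siRNA. Of these, 65 higher and 157 lower were measured on both arrays, and 78 and 40 were bounds. The highest bound was that of Hrh3, a histamine receptor gene (at least 35.5-fold higher), which was well above background on the Ruvbl2 siRNA LPS array alone, and the largest measured lower values were those of Urah, an enzyme of urate breakdown (5.75-fold), and Marcks, an actin-binding protein gene (5.61-fold). Cth, which makes cysteine from cystathionine, was 4.50-fold lower. Lower calls outnumbered higher ones more clearly among brighter genes: 41 higher and 112 lower were left when the brighter array had to reach a level of -2, and 24 and 70 with normexp correction and quantile normalization, for a share of higher calls of 25.5% against 42.1%. Il10 and Mmp9 were under 2-fold with the latter. Of 55 other measured probes of called genes, 51 had the same direction and 26 passed the size rule in it.

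**Figure D1:**
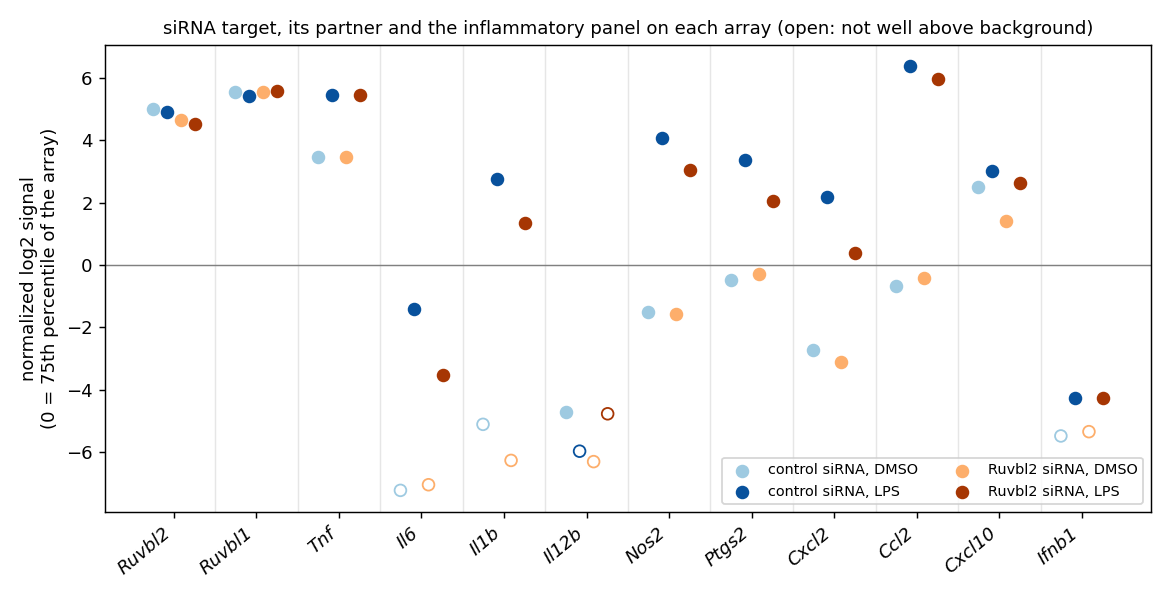
Normalized log2 signal of Ruvbl2, Ruvbl1 and the inflammatory panel on each of the 4 arrays (points, 1 array each, 0 = the array's 75th percentile; open points were not well above background). Il6, Il1b, Cxcl2, Ptgs2 and Nos2 were 4.39, 2.61, 3.48, 2.51 and 2.05-fold lower on the Ruvbl2 siRNA LPS array than on the control siRNA LPS array, while Tnf differed by 0.02 on the log2 scale.

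**Figure D2:**
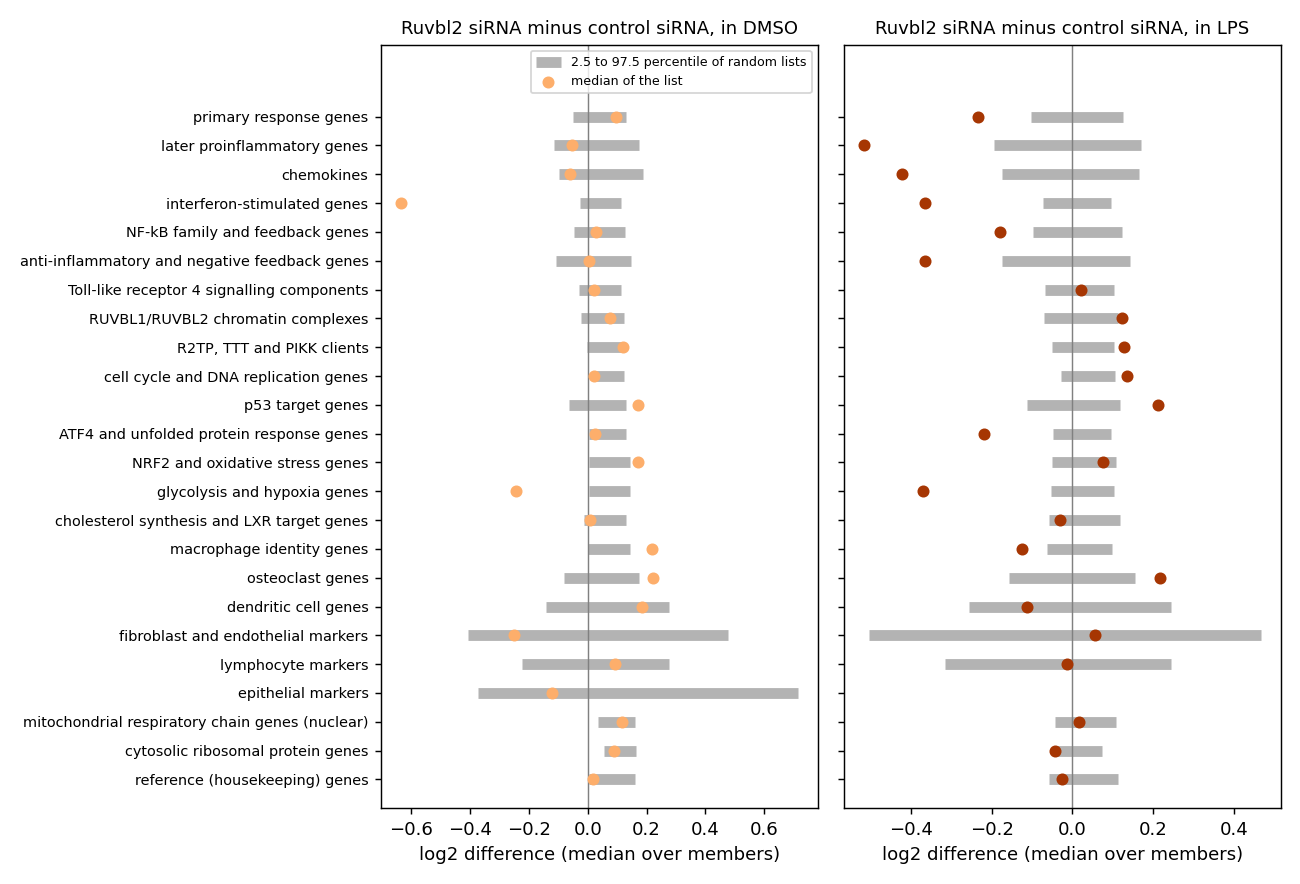
Median log2 difference between Ruvbl2 and control siRNA for each gene list (points) in DMSO and in LPS, with the central range of random lists of the same size and level (grey bars). Interferon-stimulated genes stood at -0.63 in DMSO and -0.36 in LPS, and later proinflammatory genes at -0.05 and -0.52; with spike-in scaling every DMSO point moves down alike, which turns the sign of most medians above 0 there, among them those of the p53, NRF2, macrophage identity and osteoclast lists.

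Whether the LPS response itself differed between the siRNAs was read from the difference between the 2 LPS effects, which takes out what already differed in DMSO. Later proinflammatory genes responded less with Ruvbl2 siRNA, with a median difference of -0.68 (-0.36 with spike-in scaling) and 13 of 14 members below 0, including Cfb (3.42-fold) and Saa3 (3.40-fold). Ptgs2 responded 2.86-fold less, Cxcl2 2.67-fold and Nos2 1.97-fold, the last short of the size rule, while Tnf differed by 0.03. Chemokines had a median of -0.49 (-0.17 with spike-in scaling), with Ccrl2 responding 3.05-fold less and Ccl2 1.63-fold less, the latter not past the size rule. Interferon-stimulated genes went the other way, with a median of 0.30 (0.61 with spike-in scaling) and 34 of 46 members above 0, from a lower DMSO level with Ruvbl2 siRNA. In that list 1 member was called higher and 1 lower: the interferon-induced gene Rtp4 responded 2.44-fold more and Cd274, the gene of the T cell inhibitor PD-L1, 2.37-fold less, the latter under 2-fold with normexp correction and quantile normalization and with spike-in scaling, where Oas2 passed the size rule as higher. Cxcl10 responded 1.64-fold more, which was not past the size rule, though it was with spike-in scaling.

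In all, 64 genes had a difference of at least 1 and 147 of at most -1. Among them were Ccnd2, cyclin D2 (9.23-fold less, or -3.21 on the log2 scale, against -1.33 with normexp correction and quantile normalization and -2.26 with the mean of its probes), Klra2, a lectin-like receptor (5.79-fold less), Fpr2 (4.01-fold less), Syt10 (8.40-fold more) and Hspa1b (3.89-fold more). The values of Syt10 and Klra2 lay mostly in DMSO, where Ruvbl2 against control siRNA differed by -3.11 and 1.86, and so did that of Saa3 (1.18). The ATF4 list had a median of -0.34 (-0.026 with spike-in scaling), with Pck2 responding 2.81-fold less. The primary response (-0.26), anti-inflammatory (-0.31) and macrophage identity (-0.30) lists were below their random ranges, with medians just above 0 under spike-in scaling (0.054, 0.011 and 0.016), where the median of all genes was 0.28. The NF-kB list (-0.13), the Toll-like receptor 4 list (-0.01), the RUVBL complex list (-0.03), the p53 list (0.09), NRF2 genes (-0.09) and glycolysis genes (-0.10) were within their random ranges, all with medians above 0 under spike-in scaling. The share of called genes with a larger response was 30.3%, and 80.5% with spike-in scaling, which gave 243 against 59.

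**Figure D3:**
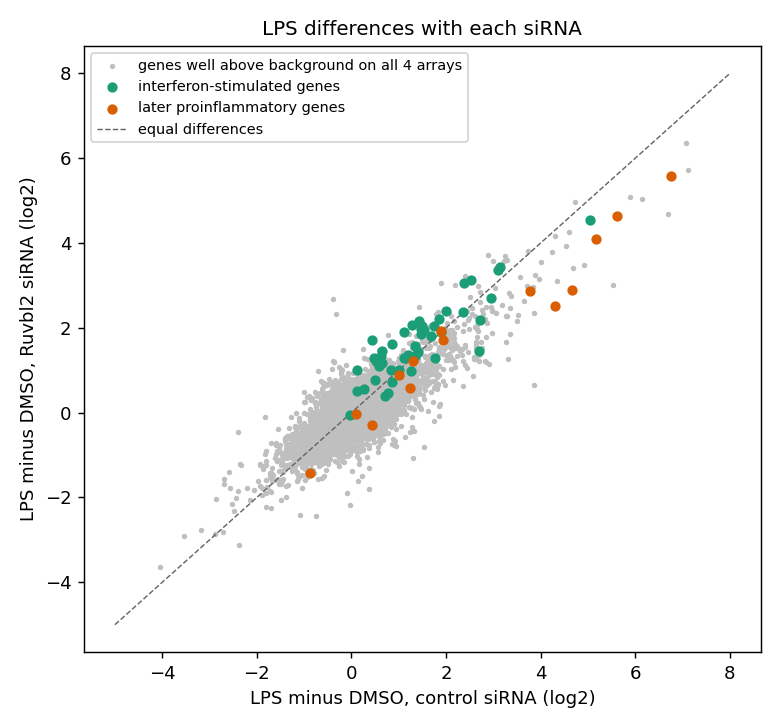
Log2 difference between LPS and DMSO with Ruvbl2 siRNA (vertical) against control siRNA (horizontal) for the 12471 genes well above background on all 4 arrays (grey), with interferon-stimulated genes in green and later proinflammatory genes in orange; the dashed line marks equal differences. The later proinflammatory genes sit mostly below the line (median difference -0.68) and the interferon-stimulated genes mostly above it (0.30).

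Some genes differed between the siRNAs whether or not LPS was given. In all, 27 genes passed the size rule in the same direction in DMSO and in LPS, from pairs of arrays that share none. Of these, 11 were higher, where 0.428 would be by chance, and 16 lower, where 0.682 would be. The chance figures take every gene as equally likely to be called. Calls gathered among dim genes, most clearly in DMSO, so these figures may be too low. The higher ones included Epha2 (log2 differences of 1.34 in DMSO and 2.27 in LPS), Phlda3 (1.41 and 2.05), Ctsk (1.17 and 1.71) and Cd207 (2.53 and 1.97). The lower ones included Isg20 (-1.28 and -1.83), Oasl2 (-1.28 and -1.02), Atf3 (-1.18 and -1.86), the apolipoprotein L gene Apol9b (-1.46 and -1.02) and Sdc3, a heparan sulphate proteoglycan (-1.68 and -1.55). Across 12471 genes the siRNA differences in the 2 treatments had a Pearson r of 0.35 and a Spearman rho of 0.32, and 3 genes passed the size rule in opposite directions. With normexp correction and quantile normalization 12 genes were shared in direction, and Ctsk, Cd207 and Oasl2 were not among them. Ctsk in DMSO also came under the size rule with spike-in scaling (0.86). Since slide row goes with the siRNA, these shared differences carry that limit in full.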

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

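No explanation was tested for the results of this part. With 1 array per group, the differences between effects given here were not tested either, and the genes were chosen after their values were seen, because they passed the size rule in opposite directions.

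Ccnd2, cyclin D2, was 1.61 higher on the log2 scale with Ruvbl2 siRNA in DMSO and differed by -1.60 in LPS, although the DMSO value was under the size rule with normexp correction and with the mean of its probes. Cd200r2, a CD200 receptor family gene, was 1.29 higher in DMSO and differed by -1.05 in LPS. Plxnb3, a semaphorin receptor gene dim on 1 array of each pair, had bounds of 1.12 in DMSO and -1.46 in LPS. For the LPS effects, Col9a2, a collagen gene, had 1.08 with control siRNA, against an undetected DMSO value, and -1.23 with Ruvbl2 siRNA. Pi16, a peptidase inhibitor gene, had 1.30 and -1.08. With normexp correction and quantile normalization none of the 5 genes kept both calls: Cd200r2 had -0.04 and -0.32, Plxnb3 0.23 and -0.34, Col9a2 0.17 and -0.27, and Pi16 1.04 and -0.89. With spike-in scaling the DMSO values of Cd200r2 (0.98) and Plxnb3 (0.81) and the Ruvbl2 siRNA values of Col9a2 (-0.86) and Pi16 (-0.71) came under the size rule, as both values of Plxnb3 did with the mean of its probes (0.74 and -0.82). Macrophage identity genes lay above their random range in DMSO and below it in LPS for Ruvbl2 against control siRNA, with medians of 0.22 (-0.093 with spike-in scaling) and -0.12.

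Probes without a gene symbol, which no comparison used, also held differences past the size rule. With LPS, 327 were higher and 278 lower with control siRNA, and 292 were higher and 268 lower with Ruvbl2 siRNA. For Ruvbl2 against control siRNA, 149 were higher and 48 lower in DMSO, and 167 were higher and 112 lower in LPS. The largest of these, 11.61 for A_55_P2273705 in LPS, came from a spot that the scanner software marked as non-uniform on the Ruvbl2 siRNA LPS array. The E1A spike-ins were 0.27 higher on the Ruvbl2 siRNA DMSO array than on the control siRNA DMSO array.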

How the results depend on the processing

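Spike-in scaling, the filter on the brighter array and the version with dim values at the floor were chosen after seeing the data. Leaving out a replicate could not be run with 1 array per group, and no paired analysis was possible because every group holds 1 array. Saturated spots did not occur, so that part of the spot filter moved nothing. The medians of later proinflammatory, primary response and interferon-stimulated genes for the siRNA difference in LPS kept their direction and stayed outside the random range under every alternative run, including random lists matched on the control LPS array. Counts are given as higher and lower, in the order LPS with control siRNA, LPS with Ruvbl2 siRNA, siRNA in DMSO, siRNA in LPS and difference in LPS response. The cause was not tested where none is given.

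The normexp correction added an offset of 50 to the signals, while the median processed signal was 21.2 to 28.0 on the 4 arrays. Log2 differences of dim genes therefore shrink in that setting by construction. A dim gene that comes under the size rule there is not thereby shown to be unchanged. With normexp correction and quantile normalization the counts were 451 and 150, 298 and 117, 14 and 24, 24 and 70, and 14 and 51. The siRNA effects then shared 12 genes in direction and the LPS effects 323. With no filter on dim genes they were 1336 and 794, 1151 and 978, 766 and 575, 645 and 765, and 918 and 1342, and the shared genes were 207 and 828, because differences of dim values then count. With genes well above background on all 4 arrays alone, the siRNA counts moved most. That filter drops every bound against a dim array. Bounds made up 82 of the 136 higher and 16 of the 72 lower calls in DMSO, and 78 of 143 and 40 of 197 in LPS. The siRNA counts moved to 45 higher in DMSO, where lower calls then outnumbered higher ones, and to 52 higher and 117 lower in LPS. With the brighter array at a level of -2 or more, LPS with Ruvbl2 siRNA gave 366 and 160, siRNA in DMSO 26 and 34, siRNA in LPS 41 and 112 and the difference 35 and 96, and the siRNA effects shared 17 genes. The size threshold of 0.58 gave 1622 and 1119, 1246 and 1081, 506 and 339, 525 and 715, and 375 and 669, and that of 2 gave 229 and 26, 160 and 34, 26 and 7, 24 and 15, and 2 and 8, as a lower or higher threshold must. With dim values at the floor the difference had 157 higher and 354 lower, since genes dim in DMSO then count.

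Spike-in scaling shifts every gene of a comparison alike. It gave 1104 and 119 for LPS with Ruvbl2 siRNA, 68 and 221 for siRNA in DMSO and 243 and 59 for the difference, and the siRNA effects shared 44 genes. It turned the sign of list medians, though not their place among random lists, which shift with them: primary response (0.054), anti-inflammatory (0.011), macrophage identity (0.016) and osteoclast genes (0.093) for the difference; p53 (-0.14), NRF2 (-0.14), macrophage identity (-0.093) and osteoclast genes (-0.09) for siRNA in DMSO; and cholesterol (0.22), mitochondrial (0.20) and ribosomal protein genes (0.22) for LPS with Ruvbl2 siRNA. The Ruvbl2 difference in DMSO was -0.65 with spike-in scaling and -0.44 with the mean of its probes, and in LPS -0.47 with normexp correction and quantile normalization and -0.26 with the mean of its probes. Signal over background limits the rest: differences of genes below a level of -2 carry a technical SD of 0.27 or more, and genes dim on both arrays were not compared.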

Other observations

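All tests of explanations in this part were chosen after the result was seen, and the gene lists were fixed before. Of 18 fibroblast and endothelial, 20 lymphocyte and 14 epithelial markers, 5, 8 and 3 could be compared between the siRNAs in LPS, and the medians of the lists with at least 5 members lay within their random ranges in every comparison. Single markers did pass the size rule with LPS and control siRNA: Fap, a fibroblast protease gene, was 3.11-fold higher, Kdr, an endothelial receptor gene, 3.94-fold and Lck, a lymphocyte kinase gene, by 1.32 on the log2 scale, and Vwf, an endothelial gene, was at least 2.29-fold lower. In LPS, Vwf was at least 2.71-fold higher and Kdr 2.11-fold lower with Ruvbl2 siRNA. Of these, all but Lck were under 2-fold with normexp correction and quantile normalization. Dendritic cell genes also lay within their random ranges, with medians of 0.18 in DMSO (negative with spike-in scaling) and -0.11 in LPS for the siRNA difference. Reference genes had medians of 0.02 and -0.03 there, the former negative with spike-in scaling, and 0 of 23 passed the size rule. B2m, an interferon-inducible part of class I antigen presentation, was 1.28-fold lower in DMSO and 1.39-fold lower in LPS with Ruvbl2 siRNA, not past the size rule. Larger shifts of reference genes went the other way: Polr2a was higher by 0.59 on the log2 scale in DMSO and by 0.75 in LPS, and Tfrc by 0.68 in LPS.

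LPS went with small shifts of housekeeping programmes. Cholesterol synthesis and LXR target genes had medians of -0.17 with control siRNA and -0.15 with Ruvbl2 siRNA, and nuclear genes of the respiratory chain -0.09 and -0.17, all below their random ranges, while the values with Ruvbl2 siRNA turn positive with spike-in scaling. With Ruvbl2 siRNA the cholesterol list came within its range with normexp correction, quantile normalization or cyclic loess, and the respiratory chain list with the mean of probes. Ribosomal protein genes had -0.03, within the range, and -0.15, below it, with the same turn for both and, for the latter, a place within the range with normexp correction, quantile normalization or cyclic loess. Cell cycle genes had -0.09 with control siRNA, below the range, and 0.06 with Ruvbl2 siRNA, within it. ATF4 and unfolded protein response genes were above the range with control siRNA (0.33, Trib3 5.29-fold higher) and within it with Ruvbl2 siRNA (0.00, above 0 with spike-in scaling). Macrophage identity genes had 0.15 with control siRNA, above the range but within it with cyclic loess, and p53 targets 0.18 with Ruvbl2 siRNA, above the range but within it with the mean of probes. The RUVBL complex list had -0.16 with control siRNA, below its range. In the difference of LPS responses, the R2TP list (0.07) and the cell cycle list (0.08) were above their ranges and osteoclast genes below theirs (-0.22, positive with spike-in scaling), though within it with normexp correction, quantile normalization or cyclic loess.

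The first pattern is that LPS-induced genes as a whole, not the inflammatory lists alone, were lower on the Ruvbl2 siRNA LPS array than on the control siRNA LPS array. Of 443 genes at least 2-fold higher with LPS on average over both siRNAs, 366 lay below 0 there. In DMSO 233 lay below 0, with a median of -0.03 against -9.4e-04 to 0.05 for sets of the same level. Their difference in LPS response had a median of -0.37 against -0.07 to -5.0e-04. With spike-in scaling the medians were -0.35 in DMSO, -0.40 in LPS and -0.055 for the difference. Array scaling or compression of bright signals is argued against, since the median of the induced genes in LPS, -0.41, was set against -0.03 to 0.03 for sets of genes of the same level. A weaker LPS stimulus in that culture stays open: 17.38% of the induced genes were not lower, a share that does not decide. The 199 genes lower with LPS stood higher on that array, with a median of 0.19. In DMSO, where no LPS was given, their median was already 0.09 (-0.22 with spike-in scaling). Tnf, with a difference of 0.02 on the LPS arrays, goes the other way. Interferon-stimulated genes do not decide. Their LPS response was larger with Ruvbl2 siRNA, with a median of 0.30, but from a lower DMSO level, and they were lower on that LPS array too. A slide row effect of the same size in both treatments would cancel in the difference in LPS response. That difference, -0.37 against -0.07 to -5.0e-04, argues against such an effect for the induced genes. Spike-in scaling shifts the compared sets alike, so their order stays, though the median is then -0.055. A role of RUVBL2 in the response may also account for the pattern. It cannot be told apart from a row effect that differed between treatments or from the state of single cultures. Nor can it be told apart from effects of either siRNA that do not run through Ruvbl2, which no array here separates.

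The second pattern is that interferon-stimulated genes were lower with Ruvbl2 siRNA already in DMSO. Scaling or compression is argued against, with a median of -0.63 against -0.04 to 0.11 for lists matched on the DMSO arrays. A stronger interferon response to the control siRNA duplex than to the Ruvbl2 pool could give the same values and stays open, since Ifnb1 was well above background on 0 of the 2 DMSO arrays and there was no untransfected array. An effect of Ruvbl2 on baseline interferon signalling was not separated from it.

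The third pattern is that the difference in Ruvbl2 mRNA was small beside those in other genes. Compression of a bright probe would leave a larger fall at the dimmer Ruvbl2 probe. That probe differed by -0.33 on average over both treatments, with a technical SD of 0.17. This goes against compression but does not exclude it, since a dim probe may itself understate a fall. The SD rests in part on a level range with 1 pair of probe and array. The values of the dimmer probe, -0.55 in DMSO and -0.12 in LPS, also lay apart. Ruvbl2 was lower under its own siRNA in both treatments, which goes against an exchange of siRNA labels within 1 treatment, but the mean of its 2 differences, -0.37, lay just inside the range of -0.38 to 0.38 of 500 probes of the same level, so an exchange stays open. The correlation of 0.35 across genes between the 2 siRNA differences does not decide it either, since slide row goes with the labels. Incomplete transfection, recovery of the mRNA before harvest and a larger loss of protein than of mRNA may each apply, and no value here decides between them.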
